A study of Mus musculus with 15 samples.

How the data were processed

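Total RNA from 2 mouse non-small cell lung cancer lines, LSZ2 and LSZ4, was measured on 15 Agilent 1-colour mouse arrays, 7 from cells with a control hairpin (shGFP or shLacZ) and 8 from cells with a hairpin against Siva (shSiva1 or shSiva2). Per the labels, 200 ng of RNA was amplified and labelled with Cy3. The scanner files hold spot intensity values that the authors extracted with Feature Extraction 10.7.3.1, per the file headers: the processed signal, from which background had been subtracted and spatial trends removed, and the mean and local background signals. The deposited value table holds log2 values. Compared with the scanner files, the values are the log2 of the mean processed signal of each probe less the 75th percentile of its array, with the median of each probe over the 15 arrays set to 0. The labels do not give the authors' test, and none is repeated here.

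The fits used the processed signal of the scanner files. Control spots and spots with an outlier flag were left out, saturated spots were kept, the remaining spots of a probe were averaged, and log2 values were reduced by the 75th percentile of their array. A probe was tested if it was well above background on at least 4 arrays and missing on at most 3. Of 55681 distinct probes, 32189 passed this filter. Symbols were updated through the accession for 26582 probes, and 29099 probes kept the name in the file. A gene was represented by the probe with the highest mean value, which gave 22908 genes, 13714 of them with an ordinary symbol. Probe positions are on the mouse mm9 build, per the file headers.

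Models were fitted with limma 3.58.1 in R 4.3.3 (tables read with version 1.17.8 of data.table) over all 15 arrays, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each fit estimated 1 spread per gene over all its groups, so that a group with 1 array is assumed to vary like the others. The pooled comparison of shSiva with control and the comparison of the lines had line and arm as terms. The effect in each line and its difference between lines came from means of each line and arm. The comparisons of each Siva hairpin had line and 3 levels (control, shSiva1, shSiva2), and those with each control hairpin had line and 4 hairpins. Changes are log2 fold changes with the standard error (SE) of the fit. Values per group are means with standard deviation (SD). Where a gene was not well above background on any array of a group, its change is a bound: the mean of the brighter group against, per array, the higher of the gene's own value and the lowest signal among probes well above background. The number of arrays limits the precision of every value. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples. The numbers 1 and 2 after shGFP were read as replicates of 1 hairpin, and the labels do not say whether they are 2 hairpins.

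The following choices were made before the data were examined: the models, the filter, 24 gene lists, and the rule for named genes. That rule took Siva1, the 8 largest rises and 8 largest falls of the pooled comparison whose 4 line and hairpin groups all moved that way, the 2 members of each list with the smallest p, and the 4 largest rises and 4 largest falls of every other comparison, passing over names that are only identifiers. Other genes named as members of a list were picked among its called members after their values were seen. The lists were p53 target genes; Bcl-2 family, caspases and death receptors; mTOR pathway members; autophagy machinery; lysosome; ATF4 and integrated stress response; the unfolded protein response; glycolysis; nuclear-encoded oxidative phosphorylation; cholesterol synthesis; fatty acid synthesis; DNA replication and G1/S; mitosis and G2/M; ribosome biogenesis and Myc targets; hypoxia response; NRF2 targets; interferon-stimulated genes; NF-kB targets; MAPK pathway output; immediate early genes; mesenchymal and extracellular matrix genes; epithelial genes; lung alveolar and airway markers; and blood, immune and endothelial markers. Of their 796 entries, 723 were measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, again with an estimated correlation, and with fry, which tests against no change and not against all other genes. A list's shift is the median change of its members less the median of all genes.

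The fits were tested on simulated data. Of 67 genes given a change of 1 on the log2 scale in the pooled comparison, 50 were called, with 14 of the other genes called. The simulated noise was independent between arrays and genes, without differences by hairpin, replicate or brightness, so these rates may not hold for the real arrays. Alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the authors' value table, no filter and a filter on all arrays, the mean of all probes of a gene, the replicate number as a block, line and hairpin as a random block or as 8 means, array weights, an intensity trend with a robust prior, no line covariate, the row on the slide as a term, and each array left out in turn. A brightness covariate, the fit without the 5 arrays whose 75th percentile signal was under 600, and the fit with 4 hairpins as terms for the pooled comparison were chosen after seeing the data. The slide could not be fitted as a term because it holds the same arrays as the arm. Correlations of the hairpins' changes were set beside 20 simulations of unchanged groups against the same controls, with the same independent noise.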

Results

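Transcript levels were measured in LSZ2 and LSZ4, mouse lines derived from non-small cell lung cancer, after viral delivery of short hairpin RNAs. The study asks what the p53 target gene Siva does in these tumour cells. shSiva1 and shSiva2 target Siva, and shGFP and shLacZ are controls against genes that mouse cells do not carry. Each line and hairpin had 2 arrays, except LSZ2 with shGFP, which had 1, so that 7 control and 8 shSiva arrays were compared. The 2 shGFP arrays of LSZ4 were taken as replicates of 1 hairpin, which the labels do not state. Infected cells were kept in puromycin for 3 days, apart from the shLacZ cells, and were harvested 2 days after plating. The 75th percentile signal ran from 428 to 1029 intensity units, between 49.0% and 60.6% of spots were well above background, and 0 spots were saturated. All 7 control arrays were on 1 slide and all 8 shSiva arrays on another, so the slide and the Siva hairpins cannot be told apart. The labels also name another vector for the Siva hairpins than for either control, so the vector cannot be told apart from them either.

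The Siva1 transcript, the target of the hairpins, fell in both lines and with both hairpins. Siva1 encodes a protein linked to apoptosis. The probe used for Siva1 lies on chromosome 12 between 113885242 and 113886093, and its log2 value was 5.77 ± 0.55 (SD, n = 7) in control arrays and 3.22 ± 0.55 (SD, n = 8) in shSiva arrays. In the fit Siva1 fell by 2.52 on the log2 scale (SE 0.26, adjusted p = 3.19e-05), which left 17.4% of the control level, and 8 of 8 shSiva arrays lay below every control array of their line. The other Siva1 probe, on chromosome 12 between 113887275 and 113887334, read 5.54 ± 0.53 (SD, n = 7) in control and 3.21 ± 0.51 (SD, n = 8) in shSiva arrays. With shSiva1 13.0% of the Siva1 signal remained and with shSiva2 23.4%, a difference of 0.84 (SE 0.29) on the log2 scale that did not pass the test (adjusted p = 0.0534).

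**Figure D1:**
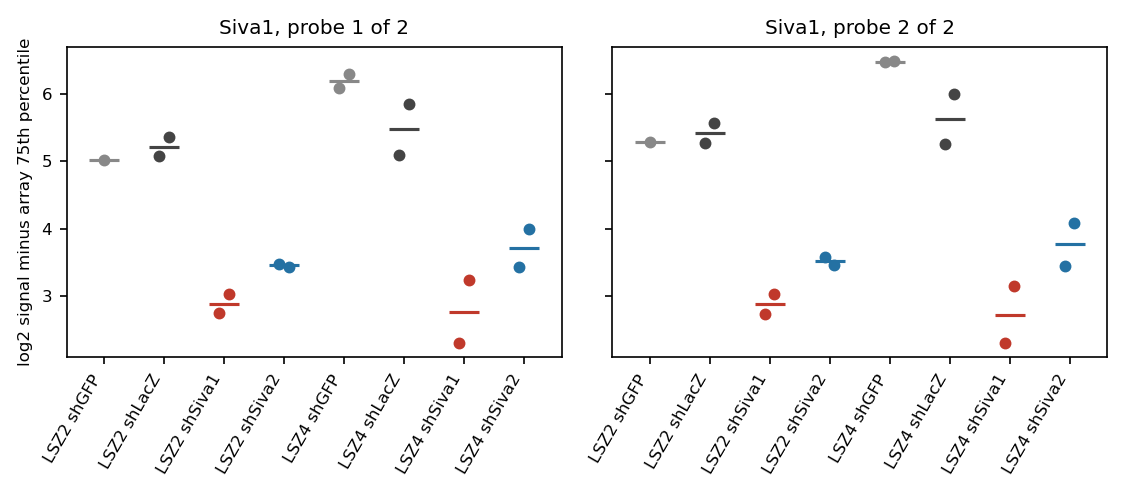
Log2 signal of both Siva1 probes, relative to the 75th percentile of each array, by line and hairpin, with points for single arrays and lines for means. For the probe used in the fits, control arrays averaged 5.77 and shSiva arrays 3.22.

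With a Siva hairpin, Timp3, Pitpnm3, Fam20a, Thbs1 and Pla2g7 were among the genes that rose most. Timp3, an inhibitor of matrix metalloproteinases (chromosome 10, 85811696 to 85811755), rose by 6.88 (SE 0.49, adjusted p = 1.2e-06) on the log2 scale, from a level well above background on 4 of 7 control arrays. Thbs1, which encodes the matrix glycoprotein thrombospondin, rose by 4.01 (SE 0.42, adjusted p = 3.57e-05) and was well above background on 5 of 7 control arrays. Pitpnm3 rose by 4.97, Fam20a, a secreted protein needed for enamel formation, by 4.30, and the phospholipase gene Pla2g7 by 3.75, although only 1, 3 and 3 of the 7 control arrays measured them. Each of these 5 genes was higher in 8 of 8 shSiva arrays than in every control array of its line. The rule that picked them required all 4 line and hairpin groups to rise, so this agreement is partly set by the choice. Ccn4 and Ccn5, which encode matricellular proteins, and Stra6, a receptor for retinol-binding protein, were on none of the 7 control arrays well above background and were at least 4.07-fold, 3.93-fold and 3.61-fold higher with shSiva. Ccn4, Ccn5 and Stra6 were measured on 6, 4 and 6 of the 8 shSiva arrays.

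Among the genes that fell were Ffar4, a receptor for long-chain fatty acids, and Aass, the first enzyme of lysine breakdown. Aass fell by 2.43 (SE 0.16, adjusted p = 5.14e-07) and Ffar4 changed by -2.73 (SE 0.33, adjusted p = 0.000109) on the log2 scale, each below every control array of its line in 8 of 8 shSiva arrays. Here too the rule required all line and hairpin groups to fall. The cytochrome P450 genes Cyp2c65 and Cyp2c66 changed by -2.85 and -2.59, and Alpi, an intestinal alkaline phosphatase, by -2.21. Lrrc26, a channel subunit, and the transcription factor gene Tcf23 changed by -2.42 and -2.36, with adjusted p = 0.0333 and 0.0475. With shSiva2 alone Lrrc26 and Tcf23 read -0.80 and -0.65 (adjusted p = 0.214 and 0.364), Cyp2c65 read -1.48 (adjusted p = 0.0614) and Ccn5 did not pass (adjusted p = 0.0544), so that these 4 passed with shSiva1 alone and not with shSiva2 alone. Ccn5, Lrrc26 and Tcf23 lost their call when any of 6, 10 and 10 of the 15 arrays was left out.

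Altogether 2285 of 22908 genes passed the test in the pooled comparison, 983 higher and 1302 lower, and 549 and 260 of them changed at least 2-fold. The median change of all genes was -0.12 here, -0.19 in LSZ4 and with shSiva1, 0.14 between the Siva hairpins, -0.21 against shGFP, 0.23 between the controls and -0.23 between the lines, so that list changes are given relative to it. Spike-in probes also read lower on the slide of the shSiva arrays after scaling, by a median of 0.10, against a difference of 0.00 before it. How far the scaling set the number of lower genes was not tested. Calls were 43.0% higher genes as fitted and 53.6% with normexp background correction, under which 806 genes were called. With line and hairpin as a random block 957 genes were called and with 1 mean for each of the 8 groups 292, while without LSZ4 shLacZ replicate 1 the count was 3786. Of the genes named here and refitted, Lrrc26, Tcf23, Fas, Ctsh, Cebpb, Ndufb10, Pmvk, Nsdhl, Dgat2, Acacb, Rrm2, E2f2, Aurka, Cdc20, Nip7, Pa2g4, Epha4 and Pecam1 lost their pooled calls with the random block and with the 8 means. Ccn4, Ccn5, Stra6, Cyp2c65, Cyp2c66, Alpi, Tap1, Plk2, Casp2, Ddit4l, Map1lc3a, Vldlr, Dnajb9, Ern1, Egln3, Abcc4 and Ehf were among those that lost theirs with the 8 means only.

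**Figure D2:**
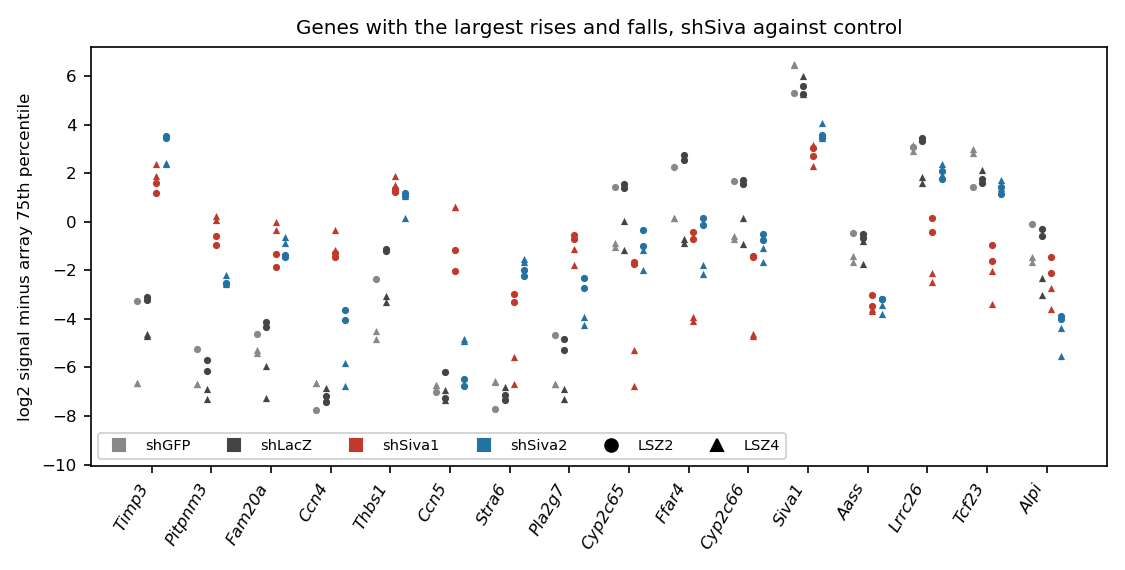
Log2 signal on each array, relative to the array's 75th percentile, for the 16 genes with the largest rises and falls with shSiva, with colours for the hairpin and symbols for the line. Timp3 and Thbs1 stood above the controls of their line on 8 of 8 shSiva arrays. The choice of genes required all line and hairpin groups to move the same way.

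Interferon-stimulated genes, which cells switch on against viruses, rose as a group with shSiva. Of 31 measured, 10 rose and 1 fell, or 15 and 1 adjusted over the list alone, and their median lay 0.63 above that of all genes (adjusted p = 3.66e-10, and adjusted p = 0.0555 with an estimated correlation). This shift was 0.60 to 1.03 with single arrays left out. The immunoproteasome subunit gene Psmb9 rose by 1.96 (SE 0.18), and another, Psmb8, was at least 2.63-fold higher, measured on 7 of 8 shSiva and none of 7 control arrays. The antiviral GTPase gene Igtp rose by 2.20 and the RNA sensor gene Ifih1 by 1.96, with 3 of 7 control arrays measuring each, while Oasl1, a 2'-5' oligoadenylate synthetase-like gene, fell by 1.12. The GTPase gene Mx2 was at least 1.23-fold higher, as none of the 7 control arrays and 5 of 8 shSiva arrays measured it. Targets of the p53 transcription factor rose too. Of 32, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone, with a shift of 0.37 (adjusted p = 5.62e-05, and adjusted p = 0.0873 with an estimated correlation). Among p53 targets, the stress-response gene Trp53inp1 rose by 1.76, the sulfatase gene Sulf2 by 1.74 and the death receptor gene Fas by 1.51. Tap1, which carries peptides for antigen presentation and is also on the interferon list, rose by 1.33, the antiproliferative gene Btg2 by 0.86 and the kinase gene Plk2 by 0.74. The ferredoxin reductase gene Fdxr fell by 0.79, and the other 25 measured p53 targets did not pass. Btg2 is also on the immediate early list and Fas on the list of death receptors. Fas was well above background on 4 of 7 control and 7 of 8 shSiva arrays.

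In the pooled comparison genes of autophagy and of the lysosome, which break down cell contents, also rose as lists. Of 39 autophagy genes, 5 rose and 1 fell, the same adjusted over the list alone, with a shift of 0.17 (adjusted p = 0.00507, and adjusted p = 0.576 with an estimated correlation). Wipi1, which acts at the forming autophagosome, rose by 1.13 (SE 0.12). Gabarapl1 and Map1lc3a encode proteins attached to the autophagosome membrane. Gabarapl1 rose by 0.78 and Map1lc3a rose in 8 of 8 shSiva arrays above every control of its line (adjusted p = 0.00358). Of 40 lysosomal genes 4 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a shift of 0.30 (adjusted p = 0.000351, and adjusted p = 0.712 with an estimated correlation). Among them the enzyme genes Ctsh and Gaa rose by 0.74 and 0.68 and the cholesterol transporter gene Npc1 by 0.50. With shSiva1 alone the lysosomal list had 2 up and 3 down and did not pass (adjusted p = 0.420), and the autophagy list passed with neither hairpin alone (adjusted p = 0.0632 for each). Against shGFP the lysosomal list had 4 up and 2 down and did not pass (adjusted p = 0.0612), whereas against shLacZ it had 6 up and 0 down, or 7 and 0 adjusted over the list alone (adjusted p = 0.00013, and adjusted p = 0.779 with an estimated correlation). Ctsh lost its call without LSZ2 shGFP replicate 1 or LSZ2 shLacZ replicate 1 (highest adjusted p = 0.0616).

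Among signalling outputs, NF-kB targets had 5 genes that rose and 3 that fell of 26, or 6 and 4 adjusted over the list alone, with a shift of 0.39 (adjusted p = 0.00507, and adjusted p = 0.315 with an estimated correlation). The adhesion molecule gene Vcam1 rose by 2.30 and the chemokine gene Cxcl5 by 2.01. Tnfaip3, an inhibitor of NF-kB, rose by 1.37 and the cytokine genes Csf1 and Lif by 1.26 and 1.03. Cxcl5 and Lif were measured on 4 and 3 of 7 control arrays, while Tnfaip2 and Bcl3 changed by -0.75 and -0.65 and the complement gene C3 also fell (adjusted p = 0.00619). Of 20 immediate early genes 4 rose and 1 fell, or 7 and 1 adjusted over the list alone, with a shift of 0.39 (adjusted p = 0.000144, and adjusted p = 0.315 with an estimated correlation). Dusp1, a phosphatase that inactivates MAP kinases, rose by 1.90, the matricellular gene Ccn1 by 1.65, Jun by 1.48 and Btg2 by 0.86, while the transcription factor gene Klf4 fell by 1.11. MAPK output genes had 3 of 27 that rose and 0 that fell, or 3 and 1 adjusted over the list alone, with a shift of 0.20 (adjusted p = 0.0461, and adjusted p = 0.712 with an estimated correlation). That call ended when any of 7 of the 15 arrays was left out (highest adjusted p = 0.101). The 3 were Spry2, which rose by 0.46, Epha4, by 1.01, and Spred3, which was at least 1.47-fold higher, with none of 7 control arrays measuring it. Spry2 and Spred3 encode inhibitors of the MAPK pathway and Epha4 an ephrin receptor. Epha4 lost its call without either LSZ4 shGFP array (highest adjusted p = 0.0550). Of 26 mesenchymal and matrix genes 4 rose and 0 fell, with the same counts adjusted over the list alone and a shift of 0.43 (adjusted p = 0.000248, and adjusted p = 0.300 with an estimated correlation). Their shift was 0.23 to 0.53 with single arrays left out. With shSiva2 alone the NF-kB and mesenchymal lists did not pass (adjusted p = 0.496 and 0.356), the former with a median of -0.01 and a mean of 0.18 relative to all genes, and the MAPK list passed with neither hairpin alone (adjusted p = 0.395 and 0.0632). The MAPK list did not pass against shGFP or in LSZ4 (adjusted p = 0.320 and 0.275), whereas it passed against shLacZ and in LSZ2 (adjusted p = 0.0457 and 0.00968, and adjusted p = 0.779 and 0.594 with an estimated correlation). The NF-kB list did not pass in LSZ2 (adjusted p = 0.0507) and passed in LSZ4 (adjusted p = 0.00371, and adjusted p = 0.337 with an estimated correlation). Besides Timp3 and Thbs1 the matrix genes that rose were the fibronectin gene Fn1 and the cadherin gene Cdh2, which rose by 2.40 and 0.98.

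In the pooled comparison the lists for DNA replication, mitosis and ribosome biogenesis were lower. Of 39 DNA replication genes 2 fell, E2f2 at -0.70 and the ribonucleotide reductase subunit gene Rrm2 at -0.49, with the same count adjusted over the list alone and a shift of -0.16 (adjusted p = 0.00507, and adjusted p = 0.712 with an estimated correlation). Of 35 mitosis genes 3 fell, or 7 adjusted over the list alone, with a shift of -0.18 (adjusted p = 0.00507, and adjusted p = 0.323 with an estimated correlation). The mitosis genes were the phosphatase gene Cdc25b, at -0.80, the kinase gene Aurka, at -0.79, and Cdc20, an activator of the anaphase-promoting complex, at -0.69. Against shGFP the mitosis list did not pass (adjusted p = 0.515), with a median of 0.13 and a mean of -0.09 relative to all genes, so that the pooled call rests on shLacZ, against which the shift was -0.36 (adjusted p = 7.77e-05, and adjusted p = 0.163 with an estimated correlation). The mitosis call ended without LSZ4 shLacZ replicate 1 (adjusted p = 0.136), and Cdc20 lost its call when any of 7 of the 15 arrays was left out (highest adjusted p = 0.0610). Of 36 ribosome biogenesis genes 2 fell, or 5 adjusted over the list alone, with a shift of -0.21 (adjusted p = 0.0033, and adjusted p = 0.712 with an estimated correlation). The 2 were Nip7 and Pa2g4, at -0.64 and -0.58. With single arrays left out the shift of the ribosome list was -0.25 to -0.13. Nip7 and Pa2g4 lost their calls when any of 10 and 11 of the 15 arrays was left out, and the other Nip7 probe changed the opposite way. In these 3 lists 0 members passed in the other direction. In LSZ2 the replication and ribosome lists did not pass (shifts of -0.04 and 0.00, the latter with a mean of -0.04, adjusted p = 0.741 and 0.774), whereas in LSZ4 they did (shifts of -0.28 and -0.41, adjusted p = 9.5e-05 and 1.46e-05, and adjusted p = 0.414 for each with an estimated correlation). The mitosis list passed in both lines (shifts of -0.25 and -0.10, adjusted p = 0.0216 and 0.0107, and adjusted p = 0.443 and 0.337 with an estimated correlation). The difference between lines was not tested for lists. Values moved with array brightness, and the 2 LSZ4 shGFP control arrays had the lowest 75th percentile signals (428 and 457). The lower lists in LSZ4 cannot be told apart from this. With shSiva2 alone the replication, mitosis and ribosome lists did not pass (adjusted p = 0.102, 0.0632 and 0.356).

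The 13 other lists did not pass the test in the pooled comparison, although single members did. Of 29 NRF2 targets 2 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0563): the glutathione transferase gene Gstm2 rose by 2.32 (SE 0.15), the transporter gene Abcc4 by 0.56, and G6pdx fell by 0.76. The NRF2 list passed the test when any of 7 of the 15 arrays was left out (lowest adjusted p = 0.00285). The NRF2 list also passed as higher in LSZ2 and against shLacZ (adjusted p = 0.00968 and 0.0281, and adjusted p = 0.813 and 0.871 with an estimated correlation). Of 38 mTOR pathway genes 1 rose and 4 fell, or 1 and 5 adjusted over the list alone (adjusted p = 0.608): Ddit4l, an inhibitor of mTOR signalling, rose by 2.30 (SE 0.37) and Deptor, another inhibitor, fell by 1.37 (SE 0.22). Of 35 Bcl-2 family, caspase and death receptor genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.463): Fas rose, and Casp2 and Fadd, which act in cell death, changed by -0.50 and -0.76. Of 28 epithelial genes 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (adjusted p = 0.686): the transcription factor gene Ehf rose by 1.33 and the tight junction gene Cldn3 fell by 1.89. Of 38 ATF4 genes 1 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.608): the lipoprotein receptor gene Vldlr rose by 2.13 and Cebpb fell by 0.84. Of 28 unfolded protein response genes 2 rose, with the same count adjusted over the list alone (adjusted p = 0.576): the chaperone gene Dnajb9 by 0.77 and the stress sensor gene Ern1 by 0.56.

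Among metabolic lists, 3 of 23 fatty acid synthesis genes fell and 1 rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.163), with Dgat2, which makes triglycerides, at -1.08 and Acacb, an acetyl-CoA carboxylase, at 1.05. Of 25 cholesterol synthesis genes 2 fell, with the same count adjusted over the list alone (adjusted p = 0.295): Pmvk at -0.80 and Nsdhl at -0.53. Nsdhl lost its call without LSZ2 shLacZ replicate 2, LSZ4 shLacZ replicate 2 or LSZ4 shSiva1 replicate 2 (highest adjusted p = 0.0536). Of 25 hypoxia genes 1 fell, also adjusted over the list alone (adjusted p = 0.932): the oxygen sensor gene Egln3 at -1.18, with Ero1a at -0.86 (adjusted p = 0.0551). Of 55 oxidative phosphorylation genes 1 fell, or 0 adjusted over the list alone (adjusted p = 0.279): the complex I subunit gene Ndufb10 at -0.81, with Atp5a1 at -0.58 (adjusted p = 0.0559). The oxidative phosphorylation list passed as lower in LSZ4 and against shGFP (adjusted p = 0.00447 and 0.0315, and adjusted p = 0.837 and 0.822 with an estimated correlation). The LSZ4 shGFP arrays were the dimmest, and these results cannot be told apart from array brightness. Of 22 glycolysis genes 0 passed, also adjusted over the list alone (adjusted p = 0.608), with Pfkl at -0.75 and Pfkfb3 at 0.68 (adjusted p = 0.0518 and 0.0628). Of 13 lung markers 0 passed, or 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.486), with Lpcat1 at 0.71 and Lamp3 at -0.49 (adjusted p = 0.0501 and 0.0542). Of 13 blood, immune and endothelial markers 1 fell, also adjusted over the list alone (adjusted p = 0.932): the endothelial gene Pecam1 at -0.66, with Cd4 at -0.45 (adjusted p = 0.0919). Relative to all genes, the hypoxia list had a median of 0.03 and a mean of -0.05 and was tested as lower. The epithelial list had a median of 0.01 and a mean of -0.02 and was tested as higher, and the marker list with Pecam1 had a median of 0.08 and a mean of 0.02 and was tested as lower. Of the members named from the lists, Fas, Ndufb10, Nsdhl, Dgat2, E2f2, Cdc20, Pa2g4, Pecam1 and Nip7 did not pass with shSiva2 alone, and Ctsh, Cebpb, Aurka, Epha4 and Nip7 did not pass with shSiva1 alone. In the pooled comparison 0 of the 11 list calls held with an estimated correlation.

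**Figure D3:**
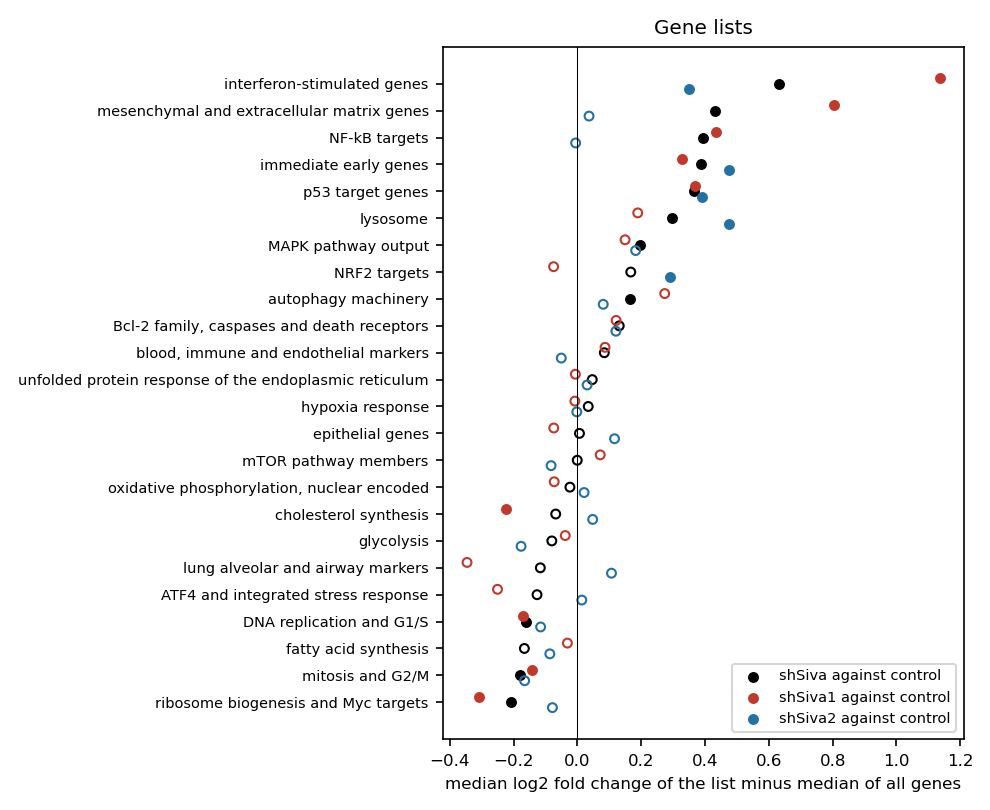
Median log2 fold change of the members of each gene list less the median of all genes, for both Siva hairpins together and for each, with filled points for an adjusted camera p under 0.05 and open points for the rest. Interferon-stimulated genes had a shift of 0.63 with both hairpins together.

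In each line taken alone, Timp3 rose and Siva1, Ffar4 and Aass fell. In LSZ2, Timp3 rose by 5.65, and Stra6 and Prr5l, which encodes a partner of the mTOR complex, were at least 7.34-fold and 5.73-fold higher, on 4 of 4 shSiva arrays and none of 3 control arrays. Pitpnm3 rose by 4.04 in LSZ2, where 1 of 3 control arrays measured it, and Siva1, Ffar4, Aass and the prolactin family gene Prl2c1 changed by -2.18, -2.79, -2.68 and -1.81. In LSZ4, Timp3 rose by 7.93 and Thbs1 by 5.09, with 1 and 2 of the 4 control arrays measuring them, and Fam20a and Pitpnm3 were at least 20.1-fold and 12.7-fold higher. Siva1 and Ffar4 changed by -2.81 and -2.68 in LSZ4, and Pramel39 and D13Ertd608e, measured on 3 of 4 control and none of 4 shSiva arrays, were at least 3.23-fold and 2.37-fold lower. Altogether 215 genes passed in LSZ2 (174 higher, 41 lower) and 1047 in LSZ4 (542 higher, 505 lower). Of these, 121 were higher and 31 lower in both, against 4.12 and 0.904 for independent lists. The lines share no arrays but share the slides, so a slide effect could also give shared genes and a correlation. The 152 shared genes became 52 to 278 with single arrays left out, 53 with the random block and 0 with the 8 means. Across genes, which are not independent replicates, the changes in both lines had a Pearson correlation of 0.65 and a Spearman correlation of 0.50. The test of a difference between lines finds few genes: in the simulated data it called 6 of 67 given a difference of 1 on the log2 scale. A count of 0 therefore does not show that the lines respond alike. With limma 0 genes differed in response between LSZ2 and LSZ4, 526 were under the threshold before adjustment, quantile normalization gave 4 genes, and leaving out LSZ4 shLacZ replicate 1 or 2 gave 2 and 3. That count was 8413 with array weights, 17 with brightness as covariate and 3 without the 5 dimmest arrays, which leaves 1 control array in LSZ4.

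Leaving out any 1 of the 7 LSZ2 arrays gave 75 to 140 genes in LSZ2, and leaving out LSZ4 shLacZ replicate 1 gave 378. Stra6, Prr5l and Prl2c1 lost their LSZ2 calls when any of 7, 7 and 6 of the 15 arrays was left out, Siva1 and Ffar4 without any 1 of the 3 LSZ2 control arrays (highest adjusted p = 0.0823 and 0.0848), and Pitpnm3 without LSZ2 shLacZ replicate 1 (adjusted p = 0.0582). With line and hairpin as a random block Siva1, Prr5l and Prl2c1 lost their LSZ2 calls and D13Ertd608e its LSZ4 call. With the 8 means Siva1, Timp3, Stra6, Prr5l, Pitpnm3, Ffar4, Aass and Prl2c1 lost their LSZ2 calls, and Siva1, Pitpnm3, Pramel39 and Ffar4 their LSZ4 calls. In LSZ4 the count was 6059 without shLacZ replicate 1, 1578 without shSiva2 replicate 2, 691 and 662 without replicate 1 of shSiva2 and shSiva1, 513 without shLacZ replicate 2, and 510 and 498 without replicates 1 and 2 of shGFP.

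Each Siva hairpin was compared with the 7 controls to see which changes both shared. With shSiva1, Ccn5, Krt17, Timp3 and Pitpnm3 were among the genes that rose most. Ccn5 and the keratin gene Krt17 were at least 24.2-fold and 24.1-fold higher, measured on 4 of 4 shSiva1 and none of 7 control arrays, and Timp3 and Pitpnm3 rose by 6.28 and 6.05. The sphingolipid enzyme gene Degs2 changed by -4.85, Cyp2c65 by -4.22, Tcf23 by -4.07 and Lrrc26 by -4.05, with 3 of 4 shSiva1 arrays measuring Degs2 and Cyp2c65. Interferon-stimulated genes rose by list, 18 up and 2 down of 31, or 18 and 3 adjusted over the list alone, with a shift of 1.14 (adjusted p = 2.48e-11, and adjusted p = 0.0133 with an estimated correlation). Among them Ifit3 rose by 4.68 and the GTPase gene Gbp2 by 3.08, with 1 of 7 control arrays measuring each. The mesenchymal and matrix list had 12 up and 2 down of 26, with the same counts adjusted over the list alone (adjusted p = 1.9e-06, and adjusted p = 0.398 with an estimated correlation), including the collagen genes Col5a1 and Col1a1, which rose by 2.63 and 2.17, the latter measured on 1 of 7 control arrays. Cholesterol synthesis genes had 9 of 25 that fell, or 10 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.743 with an estimated correlation), among them Insig1 and Mvd, at -1.08 and -0.90. NF-kB targets had 10 up and 4 down of 26, or 10 and 5 adjusted over the list alone (adjusted p = 0.000608, and adjusted p = 0.454 with an estimated correlation). The p53 list had 7 up and 3 down, with the same counts adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.599 with an estimated correlation). The immediate early list had 6 up and 2 down, or 7 and 3 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.896 with an estimated correlation). The replication, mitosis and ribosome lists had 10, 8 and 10 genes that fell, or 10, 8 and 13 adjusted over the list alone (adjusted p = 0.0192, 0.0366 and 0.00159, and adjusted p = 0.896, 0.599 and 0.760 with an estimated correlation). Altogether 5930 genes passed, 2343 higher and 3587 lower, and 8974 without LSZ4 shLacZ replicate 1.

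With shSiva2, Timp3, Stra6, Klhl30 and Gsta3 were among the genes that rose most. Timp3 rose by 7.47, Klhl30 by 4.42 and Gsta3, a glutathione transferase measured on 6 of 7 control arrays, by 4.28, and Stra6 was at least 9.43-fold higher. The water channel gene Aqp1 fell by 4.09. Klrc1 and Klrc3, which encode lectin-like receptors of natural killer cells, changed by -3.71 and -3.19 and Alpi by -3.21, with 2, 2 and 3 of the 4 shSiva2 arrays measuring Klrc1, Klrc3 and Alpi. NRF2 targets had 9 up and 0 down of 29, or 10 and 0 adjusted over the list alone (adjusted p = 7.57e-06, and adjusted p = 0.760 with an estimated correlation), and 5 of the 9 were other glutathione transferase genes, of which Gstm2 rose by 2.30. Of 40 lysosomal genes 9 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 1.91e-06, and adjusted p = 0.760 with an estimated correlation), with the enzyme gene Hexa and the activator protein gene Gm2a rising by 1.41 and 2.12. The p53 list had 7 up and 0 down, or 9 and 1 adjusted over the list alone (adjusted p = 2.45e-05, and adjusted p = 0.227 with an estimated correlation). The interferon list had 7 up and 1 down, or 8 and 1 adjusted over the list alone (adjusted p = 1.81e-05, and adjusted p = 0.209 with an estimated correlation). The immediate early list had 9 up and 2 down, or 10 and 2 adjusted over the list alone (adjusted p = 2.45e-05, and adjusted p = 0.760 with an estimated correlation). Altogether 2804 genes passed, 1372 higher and 1432 lower, and 1787 without LSZ4 shSiva2 replicate 1.

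The Siva hairpins also differed from each other. Sdc3, a cell surface proteoglycan, and Krt17 were at least 122-fold and 24.3-fold lower with shSiva2 than with shSiva1, measured on none of 4 shSiva2 and 4 of 4 shSiva1 arrays. Aqp1 and the acetylcholine receptor gene Chrna1 were lower with shSiva2, at -6.70 and -6.47, with 2 of 4 shSiva2 arrays measuring Chrna1. Degs2, Depp1 and Gsta3 were higher with shSiva2 by 5.70, 5.31 and 4.85, with 3, 3 and 2 of 4 shSiva1 arrays measuring them, and the transcription factor gene Spib was at least 11.4-fold higher. By list, NRF2 targets (9 up, 0 down, or 12 and 0 adjusted over the list alone, adjusted p = 0.000217) and cholesterol synthesis genes (7 up, 0 down, or 9 and 0 adjusted over the list alone, adjusted p = 0.00373) were higher with shSiva2. Lysosomal genes (10 up, 1 down, or 11 and 1 adjusted over the list alone, adjusted p = 0.00908) and ribosome biogenesis genes (3 up, 1 down, with the same counts adjusted over the list alone, adjusted p = 0.0433) were higher too. For each of these 4 lists the adjusted p was 0.933 with an estimated correlation. Interferon-stimulated genes (5 up, 12 down, or 5 and 15 adjusted over the list alone, adjusted p = 0.000122, and adjusted p = 0.255 with an estimated correlation) and mesenchymal genes (4 up, 11 down, or 4 and 12 adjusted over the list alone, adjusted p = 0.00159, and adjusted p = 0.933 with an estimated correlation) were lower. In all 4475 genes passed, 2315 higher and 2160 lower with shSiva2.

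Against control, 1450 genes passed with both hairpins, 583 higher with both, 519 lower with both, and 348 in opposite directions, among them Aqp1, Klrc1, Klrc3, Sdc3 and Spib. The 1102 genes shared in direction became 706 to 1898 with single arrays left out (highest without LSZ4 shLacZ replicate 1), 591 with the random block and 377 with the 8 means, and those in opposite directions 222 to 507, 196 and 100. For independent lists 140 and 224 shared genes would be higher and lower. Across genes, the changes with shSiva1 and shSiva2 had a Pearson correlation of 0.290, against 0.365 in simulations of unchanged groups with the same controls, and a covariance of 0.113, against 0.0237. With the controls split, the correlation was 0.115 for shSiva1 against shGFP with shSiva2 against shLacZ and 0.237 the other way.

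**Figure D4:**
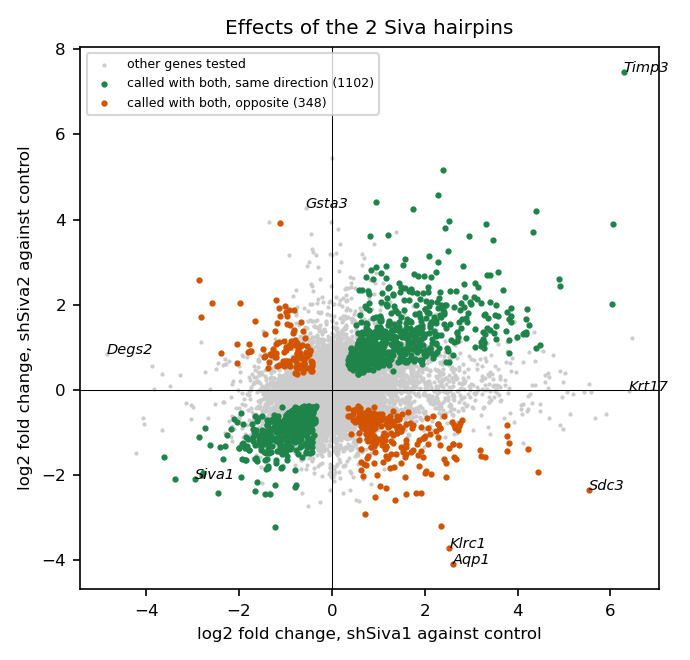
Log2 fold change of each gene with shSiva2 against that with shSiva1, each against the 7 control arrays. The 1102 genes that passed with both hairpins in the same direction and the 348 in opposite directions are coloured.

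The control hairpins differ in vector and in puromycin selection, so shSiva was compared with each. Per the labels neither control was in the vector of the Siva hairpins, so a change against both controls can still come from the vector. Timp3 and Pitpnm3 rose and Ffar4 and Cyp2c65 fell against either control. Against shGFP, Timp3, Thbs1, Pitpnm3 and Fam20a rose by 7.70, 4.91, 4.77 and 4.09, with 1 of 3 shGFP arrays measuring each of them, and Ffar4, Siva1, Lrrc26 and Cyp2c65 changed by -2.96, -2.81, -2.80 and -2.73. Against shLacZ, Timp3 rose by 6.28 and Fam20a by 4.45, with 3 and 2 of 4 shLacZ arrays measuring them, Pitpnm3 and Ccn4 were at least 14.0-fold and 4.38-fold higher, and Cyp2c65, D11Ertd49e, Cyp2c66 and Ffar4 changed by -2.94, -2.80, -2.66 and -2.57. D11Ertd49e was well above background on 1 of 8 shSiva arrays and lost its call without LSZ2 shLacZ replicate 1 or 2 or LSZ4 shLacZ replicate 1 (highest adjusted p = 0.0857), and with the 8 means Cyp2c65 lost its call against either control, D11Ertd49e against shLacZ and Capn3 between the controls. Interferon-stimulated genes rose against both, with 16 up and 1 down against shGFP, the same adjusted over the list alone, and 13 up and 1 down against shLacZ, or 16 and 1 adjusted over the list alone (adjusted p = 5.84e-11 and 5.35e-11, and adjusted p = 0.0225 and 0.0222 with an estimated correlation).

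Counts were 4690 against shGFP (1637 higher, 3053 lower) and 2575 against shLacZ (1551 higher, 1024 lower), of which 1101 were higher and 736 lower against both, 1837 in all, or 1204 to 2222 with single arrays left out and 365 with the 8 means. Without LSZ4 shGFP replicate 1 or 2, LSZ4 shSiva2 replicate 1 or LSZ2 shGFP replicate 1 the count against shGFP was 1973, 1437, 3096 and 8524. Between the controls limma called 1 gene, the calpain protease gene Capn3, at least 1.35-fold higher with shGFP on 2 of 3 shGFP and none of 4 shLacZ arrays (adjusted p = 0.0285), and 2320 genes were under the threshold before adjustment. Quantile and median scaling each called 3 genes and the trended robust prior called 0, single arrays left out gave 0 to 5, and Capn3 lost its call when any of 10 of the 15 arrays was left out. Between the controls oxidative phosphorylation genes were higher and mitosis genes lower with shGFP by list, with 0 members passing over all genes or adjusted over the list alone (adjusted p = 0.00854 for each, and adjusted p = 0.977 and 0.845 with an estimated correlation). Of the 3 shGFP arrays, the 2 from LSZ4 were the dimmest of all arrays, so these list results cannot be told apart from array brightness.

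The lines themselves were compared with the arm as covariate. LSZ2 expressed the Y-linked genes Eif2s3y, higher by 7.34 with 2 of 8 LSZ4 arrays measuring it, and Ddx3y, at least 29.9-fold higher, and more Celf2, an RNA-binding protein, by 7.65 with 4 of 8 LSZ4 arrays measuring it. Trpa1, an ion channel gene, was at least 17.6-fold higher in LSZ2. LSZ4 expressed more Sipa1l2, Kbtbd11, the homeobox gene Lbx1 and the pseudokinase gene Trib2, with changes of -5.83, -5.23, -4.43 and -4.26 for LSZ2 against LSZ4, and 5 of 7 LSZ2 arrays measured Sipa1l2. In all 4968 genes passed, 1632 higher and 3336 lower in LSZ2, or 32.9% higher against 45.5% with quantile normalization, and 480 passed without the 5 dimmest arrays, all from LSZ4. The count was 1319 to 2548 without any 1 of 10 arrays (lowest without LSZ2 shLacZ replicate 1, highest without LSZ2 shSiva2 replicate 2), 11469 without LSZ4 shSiva1 replicate 1 and 12038 without LSZ4 shLacZ replicate 1.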

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

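The test of unequal Siva1 knockdown and both tests of LSZ2 transcripts on LSZ4 arrays were chosen only after the result was seen. For 9 genes 1 array stood apart from the other 3 of its line and arm. Among LSZ4 control arrays, shLacZ replicate 1 read highest for Fas, with a gap of 0.955 of the whole range, and lowest for Dusp1 (0.979) and Rrm2 (0.839). Among LSZ2 shSiva arrays, shSiva1 replicate 2 read highest for Pmvk (0.886), Psmb9 (0.842) and Gstm2 (0.830) and lowest for Lamp3 (0.857), and shSiva1 replicate 1 read lowest for Casp2 (0.850). Timp3 was lowest on LSZ4 shSiva1 replicate 2 (0.912) among LSZ4 shSiva arrays. Of 186 combinations of gene and set tested 9 met this test, and chance flags about 1 in 20, or 9.3. With limma 0 of the 87 named genes differed in response between LSZ2 and LSZ4, against 526 of all genes before adjustment, and the smallest adjusted p was 0.192. This test missed most simulated differences of 1 on the log2 scale, so it does not show that the lines respond alike.

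Aqp1, Klrc1 and Klrc3 rose with shSiva1 by 2.60, 2.53 and 2.36 and changed with shSiva2 by -4.09, -3.71 and -3.19, and the Siva hairpins differed in 4475 genes. A hairpin that leaves less Siva1 would move the same genes further in the same direction, but 24.0% of the genes called with both hairpins moved opposite ways, so unequal knockdown does not account for the whole difference. The row on the slide, which shSiva1 shares with shGFP and shSiva2 with shLacZ, would give a slope of about 1 for the control difference on the Siva difference, and the slope was -0.0395. Effects of each hairpin on other transcripts, and differences between the infected cultures, remain open and were not tested. Shared controls may account for part of the overlap of 1102 genes, since the correlation of 0.290 was 0.115 and 0.237 with split controls, while the shared higher genes numbered 438 and 430 against 114 and 105 for independent lists and the shared lower genes 262 and 321 against 216 and 120. Splitting the controls does not remove a slide effect, which both Siva hairpins would share.

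Values also moved with array brightness: over 18328 genes, the first principal component of the values, with 54.3% of the variance, followed the 75th percentile signal across the 15 arrays (Pearson 0.97, Spearman 0.94, permutation p = 1e-05 for each, the smallest they can give), which was the 1 relation across samples computed. The scaling had subtracted that same signal from every value, so part of the relation is built in. The permutations do not reproduce this part, so their p-values do not show that expression followed brightness. Pearson values were 0.99 and 0.98 within the slides, 0.97 within LSZ4 and 0.95 without the 2 arrays farthest in brightness, but 0.67 within LSZ2 (permutation p = 0.0989; Spearman 0.82, permutation p = 0.0345). Degraded RNA would lower probes nearer the 5' end on the dimmer array, whereas they read higher by a median of 0.123 over the 4 pairs of replicates with the largest gap in brightness (-0.03 to 0.16 over all 7 pairs), and scaling to 1 percentile would leave little after quantile normalization, which left 92.1% of the variance of differences in those 4 pairs (90.4% to 98.5% over all 7). That variance leaves out a shift shared by all genes, so it cannot decide whether the scaling gave one. In those 4 pairs brightness differed by 0.26 to 0.72 on the log2 scale. After scaling, the brightest genes read higher on the dimmer array by medians of 0.23 to 0.66, and the dimmest differed by -0.02 to 0.55. In the LSZ4 shGFP pair, with a gap of 0.09, these medians were -0.02 and -0.11. Whether the scaling, the state of the cultures or the labelling of each sample gave such a shift was not tested, and each remains open. No biological explanation was tested.

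Celf2 and Eif2s3y, bright in LSZ2, stood highest on LSZ4 shLacZ replicate 1, shSiva1 replicate 1 and shSiva2 replicate 1. There their median was 1.44%, 1.05% and 0.974% of the LSZ2 signal, and it was 0.122% to 0.322% on the other 5 LSZ4 arrays. Eif2s3y was measured on fewer LSZ4 arrays than these 3 and Celf2 on more, so neither was measured on exactly these arrays. Each of these 3 arrays lay next to an LSZ2 array on its slide, so LSZ2 material or a leak between neighbours may be the source. A wider set of 22 transcripts, taken up after those values were seen, read 3.75%, 18.2% and 9.99% on these 3 arrays, a median of 9.99%, and 2.36%, 7.80% and 6.46% on the other array of each pair, so that shLacZ replicate 1, with a neighbour, lay below 2 arrays without one. Both sets were chosen as transcripts seen on neither LSZ4 shGFP array, which fixes low shares there, the overlap compares arrays of other hairpins and slides, where LSZ4 cells may differ in expression, and each of the 3 arrays was also the brighter of its pair. For these reasons, which were also found only after the values were seen, the tests were void, and neither source can be excluded or told apart from expression by LSZ4 cells.

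The arrays were also split into other groups of the same sizes and fitted again, with 100 splits drawn where there were more. These splits take single arrays as the units, and with 1 mean per line and hairpin LSZ2 gave 0 genes and with a random block 73. On single arrays the real split alone gave as many genes for the pooled comparison (1 of 100, real 2285, highest other 83) and for LSZ2 (1 of 35, real 215, highest other 0). So it did for shSiva2 against shSiva1 (1 of 35, real 4475, highest other 2), for shSiva against shLacZ (1 of 100, real 2575, highest other 374) and for LSZ2 against LSZ4 (1 of 100, real 4968, highest other 164). Fewer than 5 in 100 splits gave as many for shSiva1 (3 of 100, real 5930, highest other 10722), shSiva2 (3 of 100, real 2804, highest other 12913) and shSiva against shGFP (2 of 100, real 4690, highest other 7738). Some of those called more genes than the real one, so chance is not excluded there. Against shGFP and shLacZ the other splits drew the Siva hairpin labels at random while the real fit kept them, which favours the real split. These shares were not adjusted over the comparisons. Chance cannot be excluded in LSZ4 (4 of 35, real 1047, highest other 12495) or between shGFP and shLacZ (5 of 35, real 1, highest other 12230). For the difference between lines 0 genes were called, so every split gives as many (100 of 100, highest other 7915) and the count says nothing on chance. The highest splits of shSiva1, shSiva2, shGFP, LSZ4 and the control comparison parted dim LSZ4 arrays from the rest, which points to a structure of the samples along brightness, and with brightness as covariate, an alternative chosen after seeing the data, 3949 genes were called in LSZ4. Within LSZ4 the differences between replicates 1 and 2 correlated in each pair of groups (0.27 to 0.89). The highest LSZ4 split put replicate 1 of shLacZ, shSiva1 and shSiva2 together with replicate 2 of shSiva1, and shGFP replicate 1 on the other side. With the replicate number as a block 1460 genes were called in LSZ4.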

How the results depend on the processing

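The brightness covariate, the fit without the 5 dimmest arrays and the fit with 4 hairpins as terms were chosen only after the result was seen. Siva1 fell under each alternative run, and among 126 results for named genes 0 turned direction under the alternatives set beforehand, 62 kept their side of the threshold in each and 64 lost or gained a call in at least 1, with 22 lost under the random block and 52 under 1 mean per line and hairpin. No value that passed its test reversed in these fits, but shifts of lists that did not pass changed sign as single arrays were left out: hypoxia -0.08 to 0.10, epithelial -0.03 to 0.05, blood, immune and endothelial markers -0.00 to 0.13, mTOR -0.03 to 0.03, oxidative phosphorylation -0.06 to 0.04 and cholesterol -0.12 to 0.01. Pooled calls went from 43.0% to 53.6% higher genes with normexp. Counts of genes moved more than directions did. For the changes given here the cause was not tested. Counts given without a name follow the order pooled, LSZ2, LSZ4, shSiva1, shSiva2, between Siva hairpins, against shGFP, against shLacZ and between lines, where a comparison moved more than 1.5-fold.

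Normexp background correction gave 806 genes pooled, of which 795 were among the 2285, 77 in LSZ2, 518 in LSZ4, 3917 with shSiva1, 1199 with shSiva2, 1489 against shGFP, 1145 against shLacZ, 2027 between lines and 0 between controls. Quantile normalization gave 403 in LSZ2, 4 for the difference between lines, 3887 against shLacZ and 3 between controls, and median scaling 3 between controls. Without a filter 682 genes were called in LSZ4, 8742 between lines and 0 between controls, and with a filter on all arrays, which tests fewer genes, 127 in LSZ2 and 0 between controls. The trended robust prior gave 0 between controls.

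With line and hairpin as a random block the counts were 957 pooled, 73 in LSZ2, 279 in LSZ4, 3859 with shSiva1, 1783 with shSiva2 and 1051 between lines. With 1 mean per line and hairpin, which leaves 8 values, they were 292 pooled, 0 in LSZ2, 34 in LSZ4, 2706, 1185, 2145, 822 against shGFP, 452 against shLacZ, 452 between lines and 0 between controls. Array weights gave 6551 pooled, 8317 in LSZ2, 9274 in LSZ4, 8413 for the difference between lines, 12309, 7468, 10719, 12735, 5353, 16997 between lines and 30 between controls. Without the line covariate 1480 genes were called pooled and with 4 hairpins as terms 5018.

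With brightness as covariate the counts were 6690 pooled, 1895 in LSZ2, 3949 in LSZ4, 17 for the difference between lines, 11484, 8760, 9647, 9014 against shLacZ and 972 between lines. Without the 5 dimmest arrays they were 1326 pooled, of which 1059 were among the 2285, 356 in LSZ2, 143 in LSZ4, 3 for the difference between lines, 608 against shGFP, 3 between controls and 480 between lines. This leaves 1 control array in LSZ4 and 1 shGFP array, so the counts in LSZ4, for the difference between lines, against shGFP and between controls rest on 1 array in a group.

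The replicate number as a block gave 2906 genes pooled, 251 in LSZ2, 1460 in LSZ4, 0 for the difference between lines, 7449, 3477, 5303, 9853 against shGFP, 3909 against shLacZ, 4 between controls and 6287 between lines, with Siva1 at -2.55, 10 lists, and correlations of 0.298 between hairpins and 0.686 between lines. The labels do not pair replicates by number, although replicate differences of 15 of 21 pairs of groups correlated above 0.1 (-0.39 to 0.89), and those of each pair of LSZ4 groups did (0.27 to 0.89). A block for the slide was not run, because the slide holds the same arrays as the arm.

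With an estimated correlation 0 of the 11 pooled list calls held, and fry, which tests a list against no change rather than against all genes, called 8. The correlation of the hairpins' changes, 0.290, was 0.267 with normexp and 0.251 with a filter on all arrays. The correlation between lines, 0.647, was 0.515 with normexp, 0.502 without a filter, 0.359 with array weights and 0.732 with brightness as covariate.

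For each array left out in turn the fits gave 1545 to 3786 genes pooled, 75 to 378 in LSZ2, 498 to 6059 in LSZ4, 0 to 3 for the difference between lines, 4013 to 8974 with shSiva1, 1787 to 3987 with shSiva2, 3479 to 5623 between Siva hairpins, 1437 to 8524 against shGFP, 1818 to 2942 against shLacZ, 0 to 5 between controls and 1319 to 12038 between lines. LSZ2 shGFP has 1 array, and a group left with 1 array is assumed to vary like the others. Siva1 was between -2.63 and -2.34, 9 to 12 lists passed, and the correlations were 0.263 to 0.329 between hairpins and 0.513 to 0.694 between lines. Without LSZ4 shLacZ replicate 1 the pooled, LSZ2, LSZ4, shSiva1, shSiva2 and line counts were at their highest in these fits. Signal over background limits what can be measured: 49.0% to 60.6% of spots were well above it.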

Other observations

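The genes and values in this part were chosen only after the result was seen. With shSiva1, 13 of 38 ATF4 and stress response genes fell and 3 rose, or 14 and 3 adjusted over the list alone, although the list did not pass (adjusted p = 0.181). Slc6a9, a glycine transporter gene, fell (adjusted p = 3.02e-06), Chac1, a glutathione-degrading enzyme gene, changed by -1.28 (SE 0.27) and the asparagine synthetase gene Asns by -0.73 (SE 0.21). With shSiva2 the same genes read -0.40, -0.42 and -0.04 and did not pass. Of 13 lung markers 6 fell and 1 rose with shSiva1, or 8 and 1 adjusted over the list alone (adjusted p = 0.112). Sftpb, a surfactant protein gene, fell by 2.83 with shSiva1, where 1 of 4 shSiva1 arrays measured it, and read 1.12 with shSiva2.

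Values of 10 spike-in probes differed between slides by a median of 0.00 before scaling (-0.05 to 0.07) and -0.10 after it (-0.15 to -0.03). The 7 pairs of replicates had correlations of 0.980 to 0.998 and standard deviations of differences of 0.181 to 0.671, the widest between the LSZ4 shLacZ arrays. Between the 2 arrays of a pair 0 probe values were exactly equal.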
